A study of Mus musculus with 6 samples.

How the data were processed

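RNA was sequenced from primary mouse neural stem cells, 3 libraries from Phf2 flox/flox embryos without Cre (WT) and 3 from Nestin-Cre, Phf2 flox/flox embryos (KO). Per the labels' protocols, the cells came from embryonic cortex, were enriched as neurospheres and expanded on laminin with FGF and EGF, and the libraries were made from fragmented mRNA primed with random hexamers. The authors deposited whole-number counts per gene symbol, not normalized. Per the submitters' processing notes, the tools were FastQC, cutadapt, Trim Galore, Bowtie2 and RSEM with the mouse build mm10. Their versions, the annotation, the strand setting and how RSEM estimates became whole counts are not given in the sources used here. The counts entered every test as deposited. Group and replicate number were taken from the sample titles, and each column matched 1 title.

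The table held 24503 gene symbols, of which 7018 had 0 counts in every library, and it held no mitochondrially encoded genes and no entries that name no gene. Total counts ranged from 33413444 to 46890314 per library. Positions, transcript lengths and GC content were taken from GENCODE vM21 on GRCm38, the assembly that mm10 names; 23334 symbols (95.2%) matched 1 gene. Coordinates are 1-based.

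Differential expression was computed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the group as factor, which left 13683 genes, and libraries were scaled by TMM. A quasi-likelihood model with robust estimation was fitted to all 6 libraries and tested with glmQLFTest, two-sided, with Benjamini-Hochberg adjustment; genes with adjusted p under 0.05 are called. Standard errors are the log2 fold change divided by the square root of the F statistic. CPM values are TMM-scaled and given as mean ± SD over n = 3 libraries per group. Because the labels do not say that the libraries came from separate cultures or embryos, all p-values measure only the spread between these samples, which may be technical.

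WT and KO libraries share the replicate numbers 1 to 3, so a fit with the replicate number as a block was set beside the unblocked one before the data were examined. The pairing was checked through the correlation, across genes, of each library's deviations from its group mean. It was 0.854 for WT 1 with KO 1, 0.604 for WT 2 with KO 2 and 0.580 for WT 3 with KO 3, all over the limit of 0.1 set for treating the numbers as pairs. The pairing thus comes from these correlations and not from the labels. The correlations across numbers 2 and 3 were as high, 0.633 for WT 2 with KO 3 and 0.578 for WT 3 with KO 2, so the structure separates number 1 from numbers 2 and 3 and does not tell numbers 2 and 3 apart. A fit with number 1 against the others as the block was therefore added after the data were examined. List members named as rising or falling were called with the block; of these, Bcas1 and Nkx2-2 alone were also called over all genes without it.

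Replicates were compared by a chi-square test per gene over genes with at least 40 counts in the 2 libraries together. KO 2 and KO 3 gave a median of 1.02, against 0.455 from counting alone, and 19.5% of genes lay over the 95% limit, against 5% from counting alone. WT 2 and WT 3 gave a median of 5.32. KO 2 and KO 3 thus differed by more than counting noise, but 2 libraries of 1 culture would do so too, and the values do not tell whether these are separate cultures. They were entered as 2 samples, as labelled, and a fit with their counts summed was added after the data were examined.

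Named genes followed a rule fixed before the data were examined: Phf2, the 10 called genes with the largest log2 fold change and the 5 with the lowest p in each direction, among genes with a mean of at least 2 CPM, with every KO library on one side of every WT library and with a symbol other than a predicted gene or clone; and up to 4 called members of each gene list by lowest p, or the 2 members with the highest CPM where fewer than 2 were called. The rule was also applied to the blocked fit, which was decided after the data were examined.

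Gene lists for pathways, gene families and cell types were fixed before the data were examined. The 38 lists with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 38 lists, without and with the replicate block. Each list was also tested by camera with an estimated correlation, by camera on ranks and by fry, which asks whether a list's members move, on balance, one way. With an estimated correlation camera rests on few residual degrees of freedom, and no list passed for KO against WT. The lowest adjusted p was 0.554 without the block and 0.677 with it. Lists with an estimated correlation under the preset 0.01, such as interferon response (0.00155) and neuron (−0.0085) with the block, lost the call too. A call lost in this setting therefore does not tell whether a list moved. The Hox list (0 tested members), the red blood cell list (0) and the microglia and macrophage list (4) were too small to test.

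Other settings were median-of-ratios and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no filter, a filter of 1 CPM in 3 libraries, no robust estimation, each library left out in turn, sex-linked genes and Phf2 left out, and glmTreat against a 1.2-fold change. The same settings with the block, and fits of numbers 2 and 3 alone, were added after the data were examined. Leaving out 1 library gives number 1 an unequal share of WT and KO. In the unblocked fit, lists that differ in number 1 can then lose or turn their call for that reason. The procedure was tested on simulated counts with 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold. For the unblocked comparison (13543 genes in the simulation) edgeR recovered 5.97%, 34.3% and 95.5% of these, with 4 false calls. DESeq2 recovered 7.46%, 47.8% and 97.0% there, with 18 false calls. For the blocked comparison (13586 genes) edgeR recovered 80.6%, 91.0% and 95.5%, with 5 false calls. In the list test on the simulated counts, the list that was moved was called and 0 of 30 random lists were. For the unblocked comparison each gene had 1 expected level over all libraries, apart from the simulated changes. The gap between number 1 and the others thus entered as independent noise, whereas WT 1 and KO 1 share it in these data. The unblocked recovery and false calls therefore do not carry over to these data. The simulated genes were drawn independently of each other. The simulation therefore does not show how often lists of correlated genes would be called falsely. The estimated correlation with the block was 0.65 for S phase and 0.92 for ribosomal proteins.

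Since no strand setting is given, reads of a gene cannot be told from those of an antisense gene over its exons. In GENCODE vM21 this applies, among genes named in the text, to Phf2, Bcas1, Gnao1, Nkx2-2, Rps6ka1, Ak5, Aldh1l1, Axin2, Brca2, Car9, Cdkn1c, Dlx1, Emx2, Eng, Fanci, Fgfr3, Fras1, Gas1, Hes5, Hhip, Hmga1, Hopx, Map2, Meg3, Myt1l, Ncapg, Nr2f1, Nrn1, Otx2, Pdgfra, Pfkp, Pole, Prom1, Runx1, Six3, Slc2a1, Tagln, Trim71 and Zfp429.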

Results

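Gene expression was measured by RNA-seq in primary neural stem cells from the cortex of mouse embryos at E13.5, grown as proliferating cultures with FGF and EGF. Control cells carried floxed Phf2 alleles without Cre (WT, n = 3 libraries), and knockout cells carried the same alleles with the Nestin-Cre transgene (KO, n = 3), Nestin being a gene of neural progenitors. The comparison asks how transcript levels change in neural stem cells when Phf2, which encodes a Jumonji-family demethylase of histone H3 lysine 9, is deleted. Total counts were 46890314, 39120340 and 46709076 in WT 1, 2 and 3 and 42503715, 42244273 and 33413444 in KO 1, 2 and 3.

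Phf2 (chromosome 13, 48801750 to 48871119, minus strand, GRCm38) was measured at 92.3 ± 15.5 CPM in WT and 51.1 ± 4.56 CPM in KO (SD, n = 3). Its counts were 4996, 3647 and 3670 in WT 1, 2 and 3 and 2315, 2041 and 1640 in KO 1, 2 and 3, so every KO library lay below every WT library. The log2 fold change was −0.85 ± 0.150 (SE), with adjusted p = 0.182 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. With the replicate number as a block it was −0.84 ± 0.0743 (SE), with adjusted p = 0.000123 in the same test. These are counts over the whole gene, and which exons the floxed alleles remove is not given in the sources used here, so reads from exons outside the deletion are included and the remaining level does not measure intact transcript. Ddx3y, Uty, Kdm5d and Eif2s3y, which lie on the Y chromosome, had at least 989 counts in each of the 6 libraries, and Xist had at most 5, so sex-linked transcripts showed 1 pattern in both groups.

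**Figure D1:**
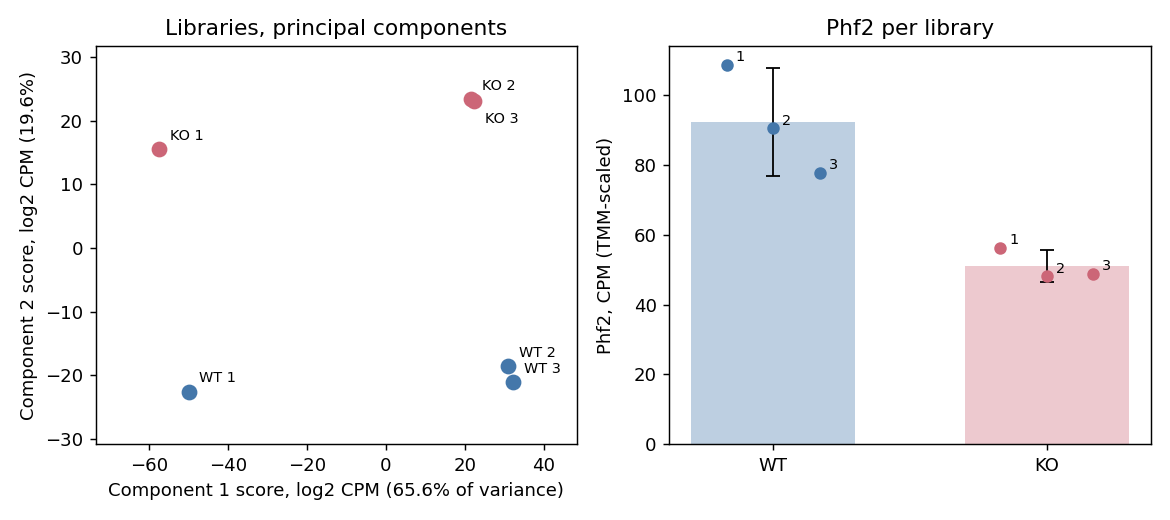
Left, scores of the 6 libraries on the first and second principal components of log2 CPM, which hold 65.6% and 19.6% of the variance; right, Phf2 in TMM-scaled CPM, with points for libraries 1 to 3, bars for the group mean and error bars for the SD (n = 3). The libraries numbered 1 lie apart from the others on the first component, WT and KO part on the second, and every KO library has less Phf2 than every WT library.

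Knockout cells had more RNA than control cells from En2, a homeobox gene of the developing midbrain and hindbrain, and from Bcas1, a marker of newly forming oligodendrocytes. They had less from Nkx2-2, a homeobox gene of the ventral neural tube and the oligodendrocyte lineage, and from Gnao1, which encodes a G protein alpha subunit abundant in neurons. En2 rose from 27.3 ± 1.68 to 65.5 ± 3.22 CPM, Bcas1 from 52.5 ± 0.915 to 120 ± 7.99 CPM, Lix1 from 30.7 ± 2.11 to 68.3 ± 0.95 CPM, and Car3, a carbonic anhydrase, from 39.8 ± 2.48 to 85.7 ± 4.17 CPM. Nkx2-2 fell from 69.2 ± 2.23 to 29.5 ± 1.73 CPM, Gnao1 from 29.9 ± 5.62 to 7.40 ± 0.371 CPM, Rps6ka1, a ribosomal S6 kinase, from 75.6 ± 3.99 to 34.7 ± 1.79 CPM, and Wbscr17, a polypeptide N-acetylgalactosaminyltransferase, from 30.5 ± 4.54 to 6.80 ± 1.01 CPM (all SD, n = 3).

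These 8 genes, 4 higher and 4 lower, were the calls among 13683 genes in edgeR's quasi-likelihood test without a block, with Benjamini-Hochberg adjusted p from 0.0316 to 0.0318. The log2 fold changes were 1.26 ± 0.102 for En2, 1.19 ± 0.0927 for Bcas1, 1.15 ± 0.0985 for Lix1, 1.11 ± 0.0990 for Car3, −1.23 ± 0.0975 for Nkx2-2, −2.01 ± 0.174 for Gnao1, −1.12 ± 0.0982 for Rps6ka1 and −2.17 ± 0.181 for Wbscr17 (SE). En2 lies on chromosome 5 (28165694 to 28172166), Bcas1 on chromosome 2 (170346991 to 170427845), Lix1 on chromosome 17 (17402672 to 17459387) and Car3 on chromosome 3 (14863512 to 14872523). Nkx2-2 lies on chromosome 2 (147177546 to 147194243), Gnao1 on chromosome 8 (93809966 to 93969388) and Rps6ka1 on chromosome 4 (133847290 to 133887797). Upper-quartile scaling called 2 higher and 4 lower. No gene was called by edgeR when WT 2, WT 3, KO 1, KO 2 or KO 3 was left out, with 499 to 864 genes at an unadjusted p under 0.05, and 21 were called without WT 1.

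With the replicate number as a block, which removes the difference between libraries numbered 1 and the others, 1340 genes were called by the same edgeR test, 456 higher and 884 lower in KO, and they included all 8 above. DESeq2 called 262 genes without the block and 1268 with it. The unblocked simulation (18 false calls, against 4 with edgeR) lacked the gap shared by WT 1 and KO 1. It therefore does not tell how many of the 262 are false. The libraries numbered 1 stood apart from the rest in both groups: 7879 genes differed between number 1 and numbers 2 and 3 by the same edgeR test with the genotype as a covariate, 3854 higher and 4025 lower. In numbers 2 and 3 alone, without a block, 743 genes were called, 251 higher and 492 lower. Of these, 741 were tested over all 6 libraries, and 711 (96.0%) went the same way between WT 1 and KO 1, which had no part in that fit. KO 2 and KO 3 were closer to each other than any other pair of libraries. With their counts summed as 1 library, no gene was called by edgeR without a block, with 495 at an unadjusted p under 0.05, and 688 were called with number 1 against the others as the block, 158 higher and 530 lower. Counts of list members with KO 2 and KO 3 summed come from this blocked fit.

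The increases named here had the largest size in the blocked fit among called genes with at least 2 CPM and no overlap between the groups, except Coro2b, named for its low p. Asb4, an imprinted gene, rose from 1.08 ± 0.235 to 5.56 ± 1.74 CPM, a log2 fold change of 2.34 ± 0.209. Otx2, a homeobox gene of the forebrain and midbrain, rose by 1.90 ± 0.103 and the homeobox gene Hlx by 1.63 ± 0.0927. Trim71, an RNA-binding protein gene, rose by 1.56 ± 0.185, Runx1 by 1.45 ± 0.134, Zfp503 by 1.34 ± 0.146 and Wnt4 by 1.29 ± 0.160 (log2, SE). Cnpy1 rose from 2.09 ± 0.635 to 5.81 ± 0.527 CPM and Coro2b, which encodes an actin-binding protein, from 88.0 ± 13.8 to 202 ± 15.7 CPM (SD, n = 3). As the rule requires, each of these lay higher in all 3 KO libraries than in any WT library. Adjusted p ranged from 1.25e-05 to 0.000834 with the block and from 0.0782 to 0.418 without it in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

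The decreases named here were chosen by the same rule, by size except Thy1, Ccdc80 and Anxa3, which were named for their low p. Cybrd1, a ferric reductase gene, went from 47.4 ± 26.5 to 6.09 ± 5.43 CPM, a log2 fold change of −3.12 ± 0.17, and Rec8, a meiotic cohesin gene, from 9.78 ± 5.20 to 1.17 ± 0.400 CPM, a change of −2.98 ± 0.185. The changes were −2.71 ± 0.219 for Ly6e, −2.48 ± 0.154 for the matrix gene Fras1, −2.41 ± 0.212 for the cGMP-dependent kinase gene Prkg1 and −2.37 ± 0.128 for Thbs2, a thrombospondin gene. They were −2.21 ± 0.175 for Ak5, −2.13 ± 0.131 for Nrn1, −2.08 ± 0.179 for Plxdc2, −1.83 ± 0.0938 for Thy1, −1.71 ± 0.0840 for Ccdc80 and −1.35 ± 0.0708 for Anxa3 (log2, SE). As the rule requires, all 12 were lower in every KO library than in any WT library. Adjusted p ranged from 1.25e-05 to 0.000124 with the block and from 0.0782 to 0.342 without it in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

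**Figure D2:**
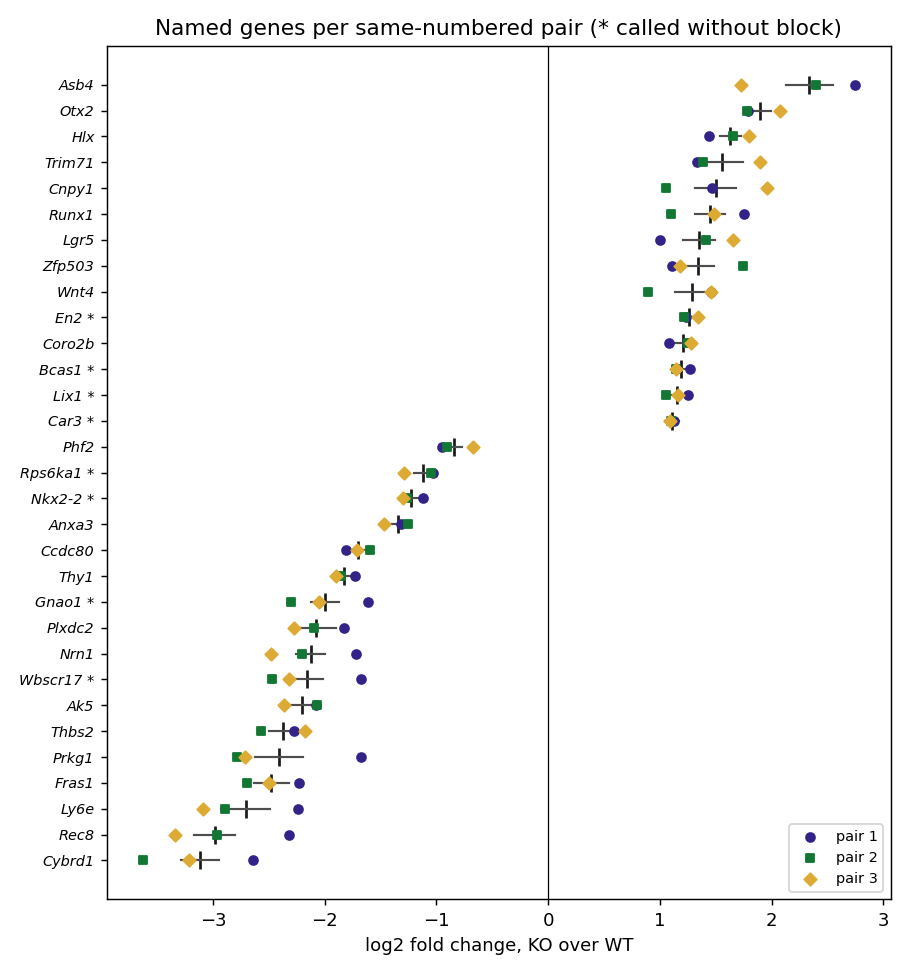
Log2 fold change of KO over WT for Phf2 and the named genes. Black ticks with lines give the blocked edgeR estimate ± SE, and coloured symbols give each same-numbered pair of libraries (pairs 1 to 3). Asterisks mark the 8 genes also called without the block. Each gene lies on 1 side of 0 in all 3 pairs, which follows from the naming rule for every gene except Phf2.

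Genes of the extracellular matrix and adhesion were lower in KO. Of 55 tested members, 25 fell and 2 rose in the blocked fit, and 6 rose and 29 fell adjusted over the list alone; without the block 0 passed over all genes and 9 fell adjusted over the list alone. Thbs2, the collagen genes Col18a1 (−1.07 ± 0.0686) and Col5a2 (−0.84 ± 0.0645) and the integrin gene Itgb5 (−0.74 ± 0.0662) had the lowest p, and Lama4 and Lamb1, both laminin genes, were the members that rose. The list's median log2 fold change was −0.28, with camera adjusted p = 5.06e-05 without the block and 3.79e-06 with it. Leaving out 1 library kept the unblocked call each time, with medians from −0.125 (without KO 1) to −0.496 (without KO 3). The call was lost with adjusted p = 0.642 with an estimated correlation without the block and 0.677 with it. With numbers 2 and 3 alone 18 members fell and 1 rose, and with KO 2 and KO 3 summed, in the fit with number 1 as the block, 21 fell and 1 rose. In the libraries numbered 1, 31 of the 55 members were lower and 14 higher than in numbers 2 and 3.

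Neuronal markers moved the same way: 8 of 21 fell and 0 rose in the blocked fit, 9 fell adjusted over the list alone, and without the block 0 passed over all genes and 2 fell adjusted over the list alone. Syt1, a synaptic vesicle gene, changed by −0.93 ± 0.0797, the RNA-binding protein gene Celf4 by −1.09 ± 0.176 and the neuronal transcription factor gene Myt1l by −2.46 ± 0.408 (log2, SE). Myt1l was at 1.10 ± 0.0718 CPM in WT and 0.208 ± 0.156 CPM in KO, while the abundant members Map2 (558 and 626 CPM in WT and KO) and Gap43 (267 and 246 CPM) did not pass. Camera gave adjusted p = 0.000118 without the block and 4.13e-05 with it. The call was lost with adjusted p = 0.642 with an estimated correlation without the block and 0.677 with it. With numbers 2 and 3 alone, and with KO 2 and KO 3 summed, 3 members fell. Of 6 excitatory cortical neuron markers, Cux2 fell and none rose, and of 9 intermediate progenitor and proneural markers Hes6 fell and none rose, and 0 members of either list were called with KO 2 and KO 3 summed.

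Markers of glia went both ways. Among 17 astrocyte markers, 7 fell and 2 rose in the blocked fit (8 fell and 2 rose adjusted over the list alone): Aldh1l1, a folate enzyme gene, went from 159 ± 47.2 to 39.1 ± 2.89 CPM and Gfap, an intermediate filament gene, from 105 ± 86.1 to 43.7 ± 34.6 CPM, while Sparcl1 went from 496 ± 255 to 1058 ± 501 CPM. Among 15 oligodendrocyte lineage markers, Bcas1 and Pdgfra rose and Nkx2-2 and Sox10 fell, the same 4 adjusted over the list alone. Of these, Bcas1 and Nkx2-2 also passed without the block, while Pdgfra (0.56 ± 0.0696) and Sox10 (−0.92 ± 0.121) did not. Among 22 neural stem cell and radial glia markers, Hopx (−1.10 ± 0.0936), Prom1 (−1.35 ± 0.130) and Lhx2 (−0.64 ± 0.0822) fell and the Notch target Hes5 (0.32 ± 0.0687) rose with the block, and 5 rose and 4 fell adjusted over the list alone. The abundant markers Vim (4591 and 4567 CPM in WT and KO) and Fabp7 (1997 and 2087 CPM) did not pass. Camera called none of these lists in either fit. With KO 2 and KO 3 summed, 5 astrocyte markers fell and 1 rose, and 3 stem cell markers fell and 0 rose. In the libraries numbered 1, 11 of the 17 astrocyte markers and 12 of the 15 oligodendrocyte markers were lower than in numbers 2 and 3.

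Transcription factors that pattern the forebrain were also split. Among 10 interneuron and ventral telencephalon markers, 4 rose and 2 fell in the blocked fit, and 5 rose and 2 fell adjusted over the list alone. The homeobox genes Six3 (1.04 ± 0.0698), Gsx2 (1.04 ± 0.105) and Dlx1 (0.98 ± 0.142) and the GABA synthesis gene Gad1 (0.93 ± 0.153) rose, while Sp8 (−2.01 ± 0.144) and Gsx1 (−1.04 ± 0.148) fell (log2, SE). Among 6 dorsal telencephalon markers, Dmrta2 (−1.01 ± 0.0972), Lhx2 and Emx2 (−0.39 ± 0.0813) fell and Nr2f1 (0.59 ± 0.0842) rose, and 2 rose and 3 fell adjusted over the list alone. Without the block no member of either list passed over all genes, while 2 ventral members rose and 1 fell, and 1 dorsal member fell, adjusted over the list alone. Camera called neither list, while fry called the ventral list with the block (adjusted p = 0.0241) and not without it (0.817).

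Targets of the Wnt pathway were higher in KO, with 6 of 15 called higher and 0 lower in the blocked fit, 8 higher and 1 lower adjusted over the list alone, and 1 higher adjusted over the list alone without the block. Lgr5, an R-spondin receptor gene, rose from 4.18 ± 1.54 to 10.4 ± 1.34 CPM, a log2 fold change of 1.35 ± 0.143. Apcdd1, Nkd1 and Fzd7 rose by 0.94 ± 0.117, 0.57 ± 0.0854 and 0.54 ± 0.0951, and the common readout Axin2 by 0.27 ± 0.0732 (log2, SE). Camera gave adjusted p = 0.00696 without the block and 0.00492 with it. The call was lost with adjusted p = 0.554 with an estimated correlation without the block and 0.677 with it, and also without KO 1 (camera adjusted p = 0.0503). Of 11 Hedgehog pathway genes, Gas1 and Cdon rose and Hhip fell, and 1 rose and 1 fell with KO 2 and KO 3 summed. Of 23 Notch pathway genes, Hes5 and Heyl rose and Dtx1 fell with the block, but with KO 2 and KO 3 summed 0 rose and 1 fell and in numbers 2 and 3 alone 0 were called. Camera called the Notch list with the block (adjusted p = 0.0446, higher) but not without it (0.373), with adjusted p = 0.677 with an estimated correlation. Of 26 genes of TGF-beta and BMP signalling, Id2, Nog and Smad7 fell and Tgfbr2 rose with the block, 1 fell and 1 rose in numbers 2 and 3 alone, and 2 fell and 1 rose with KO 2 and KO 3 summed. Camera called the list with the block (adjusted p = 0.0206, lower) but not without it (0.340), with adjusted p = 0.677 with an estimated correlation. Of 26 FGF and EGF feedback genes, Dusp4 and Spry4 rose and Hbegf and Fgfr3 fell, and 1 rose and 1 fell with KO 2 and KO 3 summed.

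Genes of the cell cycle were slightly higher in KO. With the block, 9 of 45 S phase genes and 12 of 53 G2/M genes rose and 0 fell, and 31 and 44 rose adjusted over the list alone; without the block none passed. Uhrf1 (0.36 ± 0.0747), Pole (0.36 ± 0.0875) and Chaf1b (0.32 ± 0.0782) among S phase genes and Aurkb (0.36 ± 0.0758), Ncapg (0.35 ± 0.0758) and Anln (0.34 ± 0.0772) among G2/M genes had the lowest p. The lists' medians were 0.22 and 0.23 (log2), and camera gave adjusted p = 0.000149 and 6.78e-07 without the block and 5.12e-10 and 1.35e-11 with it. The calls were lost with adjusted p = 0.90 for both with an estimated correlation without the block, and 0.677 for both with it. Without KO 1 the unblocked camera adjusted p was 0.620 for S phase and 0.139 for G2/M, with medians of 0.035 and 0.098. S phase also lost the call without WT 2 (0.308) or WT 3 (0.0981), and without WT 1 the medians were 0.48 and 0.45. These fits hold number 1 unequally in WT and KO, and number 1 was higher for both lists (medians 0.61 and 0.54, log2). With KO 2 and KO 3 summed, 0 members of either list were called, and in numbers 2 and 3 alone 10 and 18 rose. Upper-quartile scaling with the block left 4 and 8 higher. The libraries numbered 1 had higher levels than the others for 45 of the 45 S phase genes and 52 of the 53 G2/M genes, in a fit with the genotype as a covariate.

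Among 50 DNA repair genes, Fanci, Blm and Brca2 rose with the block, 12 rose and 1 fell adjusted over the list alone, and camera gave adjusted p = 0.00249 without the block and 2.31e-05 with it. The call was lost with adjusted p = 0.90 with an estimated correlation without the block and 0.677 with it, and the unblocked camera adjusted p was 0.143, 0.451 and 0.616 without WT 2, WT 3 and KO 1. In numbers 2 and 3 alone 2 rose, and 0 members were called with KO 2 and KO 3 summed. In the libraries numbered 1, 37 of the 50 members were higher and 3 lower than in the others.

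Targets of the transcription factor p53 fell, 9 of 38 in the blocked fit with 1 higher, and 17 fell and 1 rose adjusted over the list alone; without the block none passed. The stress cytokine gene Gdf15 changed from 34.8 ± 10.5 to 20.0 ± 3.99 CPM, a log2 fold change of −0.77 ± 0.0933, Ddit4l by −0.48 ± 0.0653, Ptp4a3 by −0.38 ± 0.0642 and Ccng1 by −0.36 ± 0.0660 (log2, SE), while Plk2 rose. Camera gave adjusted p = 5.18e-06 without the block and 5.88e-06 with it. The call was lost with adjusted p = 0.554 with an estimated correlation without the block and 0.677 with it. In numbers 2 and 3 alone 7 fell, and with KO 2 and KO 3 summed 3 fell. Of 17 genes of CDK inhibitors and senescence, 6 fell and 2 rose with the block, and 7 fell and 2 rose adjusted over the list alone, and without the block 2 fell adjusted over the list alone. Members that fell included the CDK inhibitor genes Cdkn2a (−0.83 ± 0.0935), Cdkn2b (−0.99 ± 0.135) and Cdkn1c (−0.59 ± 0.118) and the chromatin protein gene Hmga1 (−0.60 ± 0.0710), and Bmi1 and Lmnb1 rose. Summing KO 2 and KO 3 left 3 lower and 0 higher. Camera did not call this list in either fit.

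Imprinted genes held some of the largest decreases, with 8 of 36 lower and Asb4 higher in the blocked fit, and 9 lower and 5 higher adjusted over the list alone; without the block, 5 fell and 1 rose adjusted over the list alone and 0 passed over all genes. Dlk1 had 64, 135 and 169 counts in WT 1, 2 and 3 and 10, 7 and 1 in KO 1, 2 and 3. The noncoding genes Meg3 and Rian, which lie near Dlk1, had 20, 117 and 96 and 23, 88 and 80 counts in WT and 2, 0 and 5 and 3, 3 and 1 counts in KO. Dlk1 starts at 109452823 and Rian ends at 109661716 on chromosome 12. Grb10, an adaptor of growth factor receptors, fell from 21.4 ± 3.11 to 8.36 ± 1.63 CPM, a log2 fold change of −1.36 ± 0.0929, and the amino acid transporter gene Slc38a4 from 2.45 ± 0.246 to 0.364 ± 0.202 CPM, a change of −2.79 ± 0.323. Camera did not call the list in either fit, while fry called it with the block (adjusted p = 0.0377) and not without it (0.0801).

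Interferon response genes were lower in KO, 6 of 39 with the block and 0 higher, with 10 lower adjusted over the list alone and 1 lower adjusted over the list alone without the block. The ubiquitin ligase gene Trim25 (−0.93 ± 0.0986) and Lgals3bp (−0.87 ± 0.137) had the lowest p, and B2m (−0.23 ± 0.0672) and H2-K1 (−0.16 ± 0.0668), the members with the highest CPM, did not pass. Camera gave adjusted p = 0.000207 without the block and 8.33e-07 with it. The call was lost with adjusted p = 0.90 with an estimated correlation without the block and 0.677 with it, and without WT 2 (camera adjusted p = 0.105), WT 3 (0.0723) or KO 1 (0.430). Without KO 1 the median was 0.0078, but that fit keeps WT 1 without KO 1, and number 1 had lower levels for this list (median −0.96, log2). Between WT 1 and KO 1, 10 of the 39 members were higher in KO. With KO 2 and KO 3 summed, in numbers 2 and 3 alone and with the block under median-of-ratios scaling, 2 members fell in each case. In the libraries numbered 1, 24 of the 39 members were lower than in numbers 2 and 3. Of 49 clustered protocadherins, which encode neuronal cell surface proteins, 10 fell and 6 rose with the block, and 11 fell and 8 rose adjusted over the list alone, and without the block 5 fell adjusted over the list alone. Those that fell belong to the gamma cluster (Pcdhgb6, −0.70 ± 0.0752) and those that rose to the beta and alpha clusters (Pcdhb10, 1.19 ± 0.135), whose members share exons or near-identical sequence, so counting could split their reads. In the libraries numbered 1, 28 of the 49 were lower and 0 higher than in the others.

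Few members of the chromatin lists were called. Among 12 H3K9 demethylases and PHF2 family genes, Phf2 was the called member, and Kdm1a (180 and 190 CPM in WT and KO) and Kdm4a (173 and 172 CPM) did not pass. Of 22 H3K9 methyltransferase and reader genes none was called, and camera placed the list higher (median 0.11, adjusted p = 0.0234 without the block and 0.00702 with it), which was lost with adjusted p = 0.90 with an estimated correlation without the block and 0.677 with it, and without WT 2, WT 3 or KO 1 (camera adjusted p = 0.105, 0.689 and 0.571). The unblocked median was 0.021 without KO 1, 0.032 without WT 3 and 0.208 without WT 1. Of these 22 genes, 15 were higher and 2 lower in the libraries numbered 1 than in the others. Among 334 zinc finger protein genes 6 rose and 6 fell with the block (1 and 3 adjusted over the list alone), Zfp429 by −3.12 ± 0.310, with 1 higher and 3 lower with KO 2 and KO 3 summed, and camera placed the list higher (median 0.06, adjusted p = 0.00605 without the block and 0.00702 with it), lost with adjusted p = 0.825 with an estimated correlation without the block and 0.800 with it, and without WT 3 (camera adjusted p = 0.420). None of 26 replication-dependent histone genes and none of 7 germline genes was called.

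Among genes of growth and metabolism, 1 of 83 ribosomal protein genes (Rps4l, lower) and 0 of 73 mitochondrial respiration genes were called. Camera placed ribosomal proteins higher (median 0.08, adjusted p = 0.000615 without the block and 0.00452 with it) and mitochondrial respiration lower (median −0.08, adjusted p = 0.0234 and 0.0284), and both calls were lost with adjusted p = 0.90 for each with an estimated correlation without the block, and 0.897 and 0.912 with it. The estimated correlations of these lists with the block were 0.92 and 0.91, so adjusted p with the preset 0.01 may overstate the evidence. The unblocked call was lost for ribosomal proteins without WT 2 (camera adjusted p = 0.997) or KO 1 (0.616), and for mitochondrial respiration without WT 1 (0.302), WT 3 (0.823), KO 2 (0.354) or KO 3 (0.339). Of 54 ribosome biogenesis genes none was called, and camera placed the list higher with the block (adjusted p = 0.0446, or 0.800 with an estimated correlation) and not without it (0.566). Without KO 1 the unblocked test called ribosome biogenesis lower instead (median −0.25, camera adjusted p = 0.00129). That fit keeps WT 1 without KO 1, and number 1 had higher levels for this list (median 0.94, log2). The turn therefore does not measure the genotype alone. Camera placed the list of 25 cholesterol synthesis genes higher with the block (adjusted p = 0.0231, or 0.800 with an estimated correlation) and not without it (0.0904). Of 34 glycolysis and hypoxia genes 4 rose, among them Slc2a1, and 5 fell, among them Pfkp and Car9. Of 35 unfolded protein and amino acid stress genes Vldlr rose, and of 24 immediate early genes Nr4a1 and Nr4a2 rose and Arc and Ier5 fell. With KO 2 and KO 3 summed, 0 immediate early genes rose and 1 fell, 1 glycolysis and hypoxia gene rose and 3 fell, and 0 genes of the stress list were called.

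Among ependymal markers (7 tested) Foxj1 fell, among endothelial markers (8) Eng fell, and among neural crest and Schwann markers (5) Sox10 fell. With KO 2 and KO 3 summed 0 ependymal markers were called. Of 10 mesenchymal, meningeal and mural markers, Tagln and Col1a2 fell and Foxc1 and Twist1 rose, Twist1 with 3, 0 and 0 counts in WT 1, 2 and 3 and 28, 32 and 16 in KO 1, 2 and 3. The highest count of a Hox gene in any library was 7, that of a red blood cell gene 11 and that of a microglia and macrophage gene 231. Over all lists, Bcas1 and Nkx2-2 were the members called over all genes without the block. In all, camera called 12 of 38 lists without the block and 16 with it, none with an estimated correlation. Fry called 0 without the block and 8 with it. These were TGF-beta and BMP signalling and ventral telencephalon (fry adjusted p = 0.0241 each), Wnt targets (0.0499), and extracellular matrix, p53 targets, neuron, interferon response and imprinted genes (0.0377 each). With the block fry did not call S phase (0.236) or G2/M (0.234). The sign of the list median and of camera differed for 6 lists without the block and 4 with it, none of them called.

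**Figure D3:**
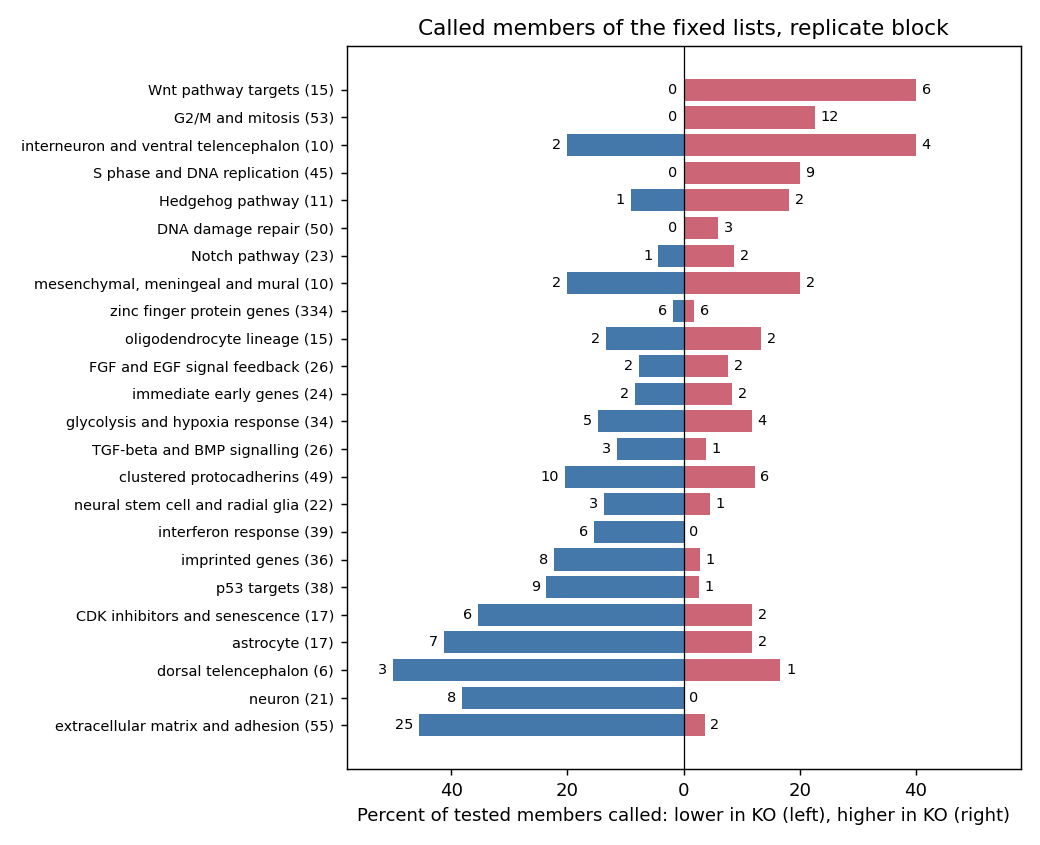
Percent of tested members of each list that were called by edgeR with the replicate block, higher in KO to the right and lower to the left, with the number of called members at each bar and the number tested in brackets. Lists with at least 3 called members are drawn; extracellular matrix genes have 25 lower and 2 higher, and G2/M genes 12 higher and 0 lower.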

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

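The replicate block, glmTreat, the choice of libraries and, without the block, DESeq2 moved the counts most, and the cause was not tested except where fewer libraries or a stricter null explain it; fits of numbers 2 and 3, of number 1 as the block and of summed KO libraries, and all alternatives to the blocked fit, were chosen after seeing the data. Against 8 calls (4 higher, 4 lower), edgeR gave 1340 (456 and 884) with the replicate block, 1445 (510 and 935) with number 1 against the others as a block and 743 (251 and 492) in numbers 2 and 3 alone, and DESeq2 gave 262 (64 and 198). Phf2 was called in these 4 settings, at −0.84, −0.85, −0.80 and −0.84 (log2). Upper-quartile scaling gave 2 higher. There were 0 calls (0 higher, 0 lower) with glmTreat against a 1.2-fold change, with 519 genes at an unadjusted p under 0.05, and with KO 2 and KO 3 summed, with 495. Leaving out 1 library gave 0 to 21 calls, 0 to 7 higher and 0 to 14 lower, and Phf2 from −0.97 to −0.71. Median-of-ratios scaling, limma-voom, no filter, a stricter filter, no robust estimation and leaving out sex-linked genes gave 7 or 8 calls. With the block, glmTreat gave 515 (96 and 419) and KO 2 and KO 3 summed gave 688 (158 and 530), and other settings gave 1037 to 1661. Of 12 lists called, 0 remained with an estimated correlation (also with the block) and 0 with fry, and leaving out 1 library gave 7 to 17. The setting with an estimated correlation rests on few residual degrees of freedom and cannot tell which lists moved. The direction of the test turned for 3 lists when 1 library was left out, with medians from −0.0046 (without WT 2) to 0.17 (without WT 3) for ribosomal proteins, from −0.16 (without WT 2) to −0.00037 (without WT 3) for mitochondrial respiration and from −0.25 (without KO 1) to 0.34 (without WT 1) for ribosome biogenesis. Number 1 had higher levels of ribosome biogenesis genes (median 0.94, log2), so leaving out KO 1 or WT 1 carries that difference into the unblocked comparison. Among named genes, 119 that did not pass without the block passed with it. Many were named because the blocked fit called them, so this count follows largely from the naming rule. In simulations at this depth the unblocked fit recovered 5.97% of 1.5-fold changes. These simulations lacked the gap shared by WT 1 and KO 1, so this share does not carry over to these data.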

Other observations

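The tests of pair 1 against numbers 2 and 3, of calls near Phf2 and of GC content with transcript length were chosen only after the result was seen. The genes named in the next 2 paragraphs, and Slc25a29 and Begain, were chosen after their values were seen.

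Libraries numbered 1 differed from numbers 2 and 3 in both WT and KO. Apln, which encodes a secreted peptide ligand, was at 233 and 131 CPM in WT 1 and KO 1 and between 6.24 and 12.9 CPM in the other 4 libraries, a 19-fold difference. Gfap, Hes5, the BMP target Id1 and the secretogranin gene Scg2 went the other way, with log2 changes of −4.52 ± 0.161, −3.71 ± 0.0777, −3.28 ± 0.118 and −5.22 ± 0.212 (SE). By camera with the genotype as a covariate, genes of ribosome biogenesis were higher in number 1 (50 of 54 called higher, adjusted p = 5.35e-17), and immediate early genes were lower (20 of 24, adjusted p = 5.08e-07), as were genes of TGF-beta and BMP signalling (19 of 26, adjusted p = 0.000591) and the Notch pathway (16 of 23, adjusted p = 0.000744). With an estimated correlation the adjusted p of these 4 lists was 0.344, 0.365, 0.323 and 0.323. The genotype effect itself differed between number 1 and the others, by an interaction term in edgeR, for 0 genes after adjustment and for 472 at an unadjusted p under 0.05. With 1 library of number 1 per group this test has little power, so it does not show that the effects are equal.

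En2 and Cnpy1, 2 of the genes that rose, are neighbours on chromosome 5, with En2 ending at 28172166 and Cnpy1 starting at 28200819. Insig1 and Rbm33, the tested genes on either side of them, had log2 changes of 0.12 ± 0.0622 and 0.26 ± 0.0820 with the block and did not pass.

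The first pattern is the set of genes called with the replicate block. Differences that arose separately in number 1 and in numbers 2 and 3 would match in direction by chance, whereas 96.0% of the genes called in numbers 2 and 3 alone went the same way in pair 1. By the labels both groups carry the floxed Phf2 alleles, so variants linked to these alleles are shared and would not separate the groups. Of the tested genes within 10 Mb of Phf2, 14.2% were called (16 of 113, exact binomial 95% interval 8.32 to 22.0%) against 9.80% elsewhere (Fisher's exact test, two-sided, p = 0.150). Variants carried with the Cre transgene would lie near its insertion site, which is not given in the sources used here, so this share does not test them. The real grouping called 8 genes without the block and was the 1 of 10 splits with as many, the highest other giving 0, and with the block it called 1340 and was the 1 of 4 splits that part all 3 pairs with as many, the highest other giving 0; 10 or 4 splits are too few for a share under 0.05. Loss of Phf2 may account for the set, as a hypothesis, but a difference between embryos, the Cre transgene and genetic background go with the groups and stay untested.

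The second pattern is the gap between number 1 and the other libraries. A difference in depth would shrink it, but after thinning all libraries to the lowest total the first component still held 66.1% of the variance, against 65.6% before. GC content and transcript length explained 3.52% of the variance of the change across genes, which argues against a library bias along these as its source. A difference in culture state, such as growth rate or density, is a candidate explanation, given the genes of S phase, ribosome biogenesis and Notch signalling that differed, but the labels give no date, passage or density, and no biological explanation was tested.

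The third pattern is the near absence of Dlk1, Meg3 and Rian RNA in KO libraries. Their levels were low in WT too, with means of 2.77, 1.79 and 1.46 CPM. Loss or silencing of the whole chromosome 12 region would lower its other genes too, but the other 12 tested genes within 1 Mb had a median log2 change of −0.0711 with the block, which argues against loss of the whole window. Slc25a29 was called lower (−0.33 ± 0.0853), and Begain, the nearest tested gene, had the lowest value (−1.35 ± 0.433; 29, 20 and 21 counts in WT and 5, 11 and 8 in KO) but did not pass, so a change that reaches beyond Dlk1, Meg3 and Rian stays open. A change centred on the imprinted genes may be involved, as a hypothesis. Whether it follows from the loss of Phf2 or from a clonal or embryo difference in imprinting was not tested, since the counts do not separate the parental alleles.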
